A study of Homo sapiens with 6 samples.

How the data were processed

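RNA was extracted from parental 22Rv1 cells and from 22Rv1 cells derived from a liver metastasis, and polyA-selected Illumina TruSeq libraries were sequenced as paired reads on a NovaSeq instrument, per the labels' protocols. RNA integrity was scored before library preparation, per the labels. Each group held 3 libraries, 6 in all, assigned from the sample titles. The series design text speaks of a further condition, which was not analysed here.

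Reads were trimmed with Trimmomatic 0.36, aligned with STAR 2.5.2b to GRCh38 and counted with featureCounts of Subread 1.5.2, per the submitters' processing notes. The parameters, the annotation release, the strand setting and whether a read pair counted as 1 or 2 are not given in the sources used here. Without a known strand setting, reads of overlapping genes on opposite strands cannot be told apart, and such overlaps with genes that hold reads are named beside the genes concerned. The authors deposited raw counts per gene for each library, as whole numbers without normalization, with gene coordinates and lengths beside them. The authors also deposited one table of TPM for the same libraries. All TPM values recomputed here from the counts and gene lengths lay within a relative difference of 1e-04 of the deposited TPM values, so both tables hold the same measurement. The TPM table ended in 391182 rows without a gene, which were left out, and a spreadsheet had turned 27 of its gene symbols into numbers; symbols were therefore taken from a table of gene identifiers, which matched 98.1% of the identifiers. GENCODE release 29 served for biotype and for the GC content of the longest transcript of each gene; 99.0% of the identifiers were found in it, and 96.3% of these had the same start and end. No other per-sample columns were present.

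Library totals ranged from 28395265 to 53275252 counts. Counts were tested with edgeR 4.0.16 (R 4.3.3): genes were filtered with filterByExpr, scaled by TMM, and fitted with robust dispersion and quasi-likelihood estimates, with the group as the only term. P-values were adjusted by the Benjamini-Hochberg method over all 19255 genes tested, with a threshold of 0.05, and a change of at least 2-fold meant a fitted log2 fold change of at least 1 in size. The common biological coefficient of variation was 9.57%. CPM values are TMM-normalised, and errors are SD over 3 libraries or the SE of the fitted log2 fold change. Levels under 1 CPM rest on few reads.

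The groups, the tests, the 24 gene lists and the rule for named genes were fixed before the data were examined. The lists were written from general knowledge of prostate cancer, of cell types that could be mixed in and of RNA handling. Each was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Chromosomes were tested with camera at both correlations. The TPM table was tested with limma on log2(TPM + 1) for genes with TPM of at least 1 in 3 or more libraries; folds on that scale understate the change of low genes.

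The genes named in the text were chosen by that rule, unless the text says otherwise. They were FOLH1, HOXB13 and FOXA1; the 5 largest rises and 5 largest falls among protein-coding genes with an adjusted p under 0.05, at least 10 CPM in the higher group and no overlap between the groups; and from each list of prostate biology or past the camera threshold up to 3, and from other lists 1, of the members past the threshold with the largest change and at least 1 CPM in the higher group. Some genes that the rule took are not reported here.

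The alternatives were RLE or upper-quartile factors or library size alone, no filter or CPM of at least 1 in 3 libraries, DESeq2 1.42.0, limma-voom, each library left out in turn, the replicate number as a block, glmTreat against a log2 fold change of 1, and for TPM a pseudocount of 0.1 or no filter. A correction for GC content by a smooth curve per library, the removal of both second replicates, the removal of chromosome 21 genes and the estimated correlation for chromosomes were added after the data were seen. No pair of libraries agreed within sampling noise, by a chi-square over genes with a mean of at least 50 counts. Each library was therefore counted as 1 replicate. This check cannot tell separate cultures from repeat library preparations of the same culture. Counts of 10 to 50 were even for 51.3 to 53.4% of genes per library; counting both mates of a pair would make most counts even. The fitting steps were tested on simulated counts drawn from the means and library sizes of this comparison, with changed genes placed among 19255. Each gene was drawn on its own, without a shift shared by the genes of a library. The edgeR step, run on 18954 genes, recovered 56.7% of 67 genes changed by 1.5-fold and 64.2% of 67 changed by 2-fold. It recovered 90.9% of 66 genes changed by 4-fold, with 7 false calls beside 38, 43 and 60 recovered genes. Far fewer genes were changed in the simulation than the 7476 called in the data. The adjusted threshold was therefore stricter there, and these shares need not hold for the real comparison.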

Results

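RNA-seq gene counts were analysed for 22Rv1, an established human prostate cancer cell line, in 2 groups of 3 libraries. One group was the parental line, and the other was 22Rv1 cells derived from a liver metastasis (called liver-derived here). The title of the series concerns the heterogeneity of prostate-specific membrane antigen (PSMA, the product of FOLH1) in metastatic prostate cancer, so the comparison addresses how PSMA RNA and the rest of the transcriptome differed between the liver-derived cells and their parent. The counts summed to 47079983, 46031158 and 50934457 in parental replicates 1 to 3 and to 53275252, 28395265 and 49522468 in liver-derived replicates 1 to 3. After a filter on low counts, 19255 genes were tested. The labels describe the libraries of a group as biological replicates and do not say whether they were separate cultures. The p-values therefore set the group difference against the spread between these libraries. The labels name no separate derivations from liver metastases, so the spread between derivations is not measured. Differences tied to the liver cannot be told apart from other differences between the 2 groups of cells.

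FOLH1 RNA was lower in the liver-derived cells. FOLH1 (ENSG00000086205; chromosome 11, 49146635 to 49208670, GRCh38, minus strand, protein coding) stood at 599, 464 and 609 CPM in parental replicates 1 to 3 and at 170, 165 and 168 CPM in the liver-derived replicates. The group means were 557 ± 81.1 and 168 ± 2.46 CPM (SD, n = 3 each), a log2 fold change of -1.73 (SE 0.11, edgeR quasi-likelihood adjusted p = 2.98e-06), or 3.32-fold lower. The paralog FOLH1B, whose sequence is close to that of FOLH1, held 187 to 225 raw reads in the parental and 31 to 83 in the liver-derived libraries. With 28395265 to 53275252 counts per library, these are few beside the reads assigned to FOLH1, and they were also fewer in the liver-derived libraries. How reads were divided between both genes is not known.

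Other genes of prostate cell-surface proteins fell as well. Of 20 tested members of the list of prostate cell-surface targets, which includes FOLH1, 4 rose, 12 fell and 4 did not pass; adjusted over the list alone, 5 rose and 12 fell. STEAP1, a prostate-enriched membrane protein, fell from 204 ± 25.4 to 21.1 ± 1.18 CPM (log2 fold change -3.28). CEACAM5, a carcinoembryonic antigen, rose from 0.161 ± 0.0823 to 3.12 ± 0.0849 CPM (4.24), and as a member of a family with similar sequences its count is uncertain. ERBB2, named after its values were seen and overlapping PGAP3 and MIEN1 on the opposite strand, rose from 120 to 226 CPM (0.91). The list was lower by camera at a preset correlation (adjusted p = 0.0236), and that call was lost with an estimated correlation (adjusted p = 0.224).

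**Figure D1:**
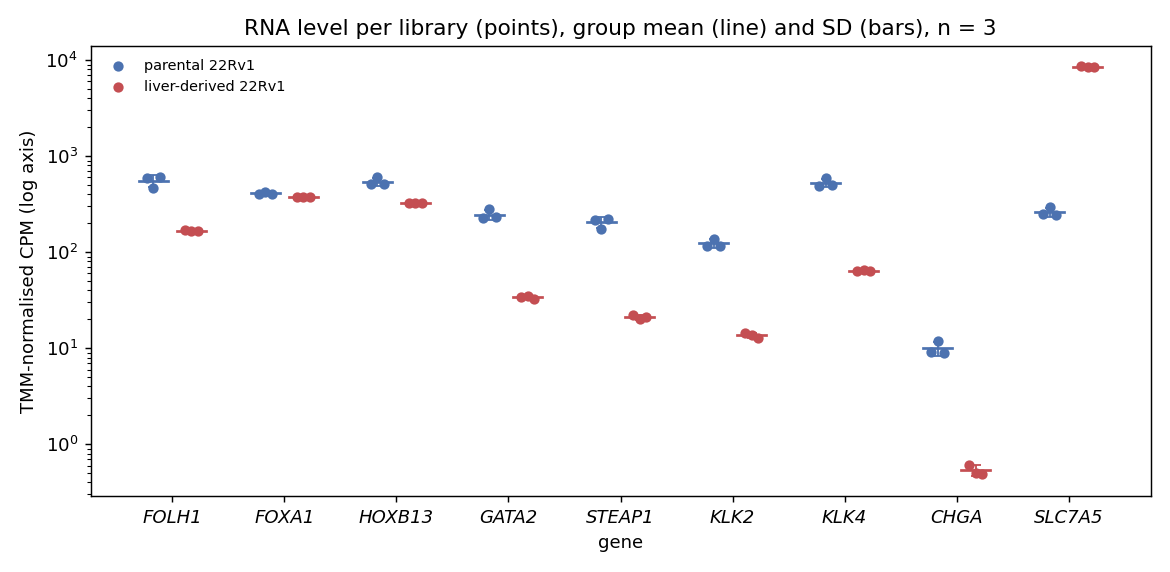
RNA levels of 9 genes in the 3 parental (blue) and 3 liver-derived (red) libraries as TMM-normalised CPM on a log axis; points are libraries, lines are group means and bars are SD. FOLH1 lay at 464 to 609 CPM in the parental and 165 to 170 CPM in the liver-derived libraries.

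Across all genes tested, 7476 differed between the groups (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), of which 3375 were higher and 4101 lower in the liver-derived cells. A change of at least 2-fold was fitted for 2658 of them, with 864 higher and 1794 lower. The first principal component held 78.6% of the variance and separated the groups. In 54.0% of the genes tested the groups did not overlap, against 10% by chance for 3 libraries against 3. Parental replicate 2 stood apart from the other parental libraries: its chi-square per degree of freedom over genes was 55.7 and 62.7 against replicates 1 and 3, whereas replicates 1 and 3 gave 2.26 and the liver-derived pairs 2.43 to 3.15. Without parental replicate 2 the test called 11870 genes, 5714 higher and 6156 lower; 7334 genes were called in both fits. A correction for GC content, added after this library was seen, called 10846 genes.

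The largest rises among well expressed protein-coding genes were in PTPRZ1, INHBA, TGM2, CEACAM6 and DSCAM. PTPRZ1, a receptor-type tyrosine phosphatase, rose from 1.80 ± 0.363 to 215 ± 1.96 CPM (log2 fold change 6.89, SE 0.13), and INHBA, the gene of the activin A subunit, rose from 4.11 ± 1.12 to 226 ± 2.11 CPM (5.77, SE 0.17). TGM2, a transglutaminase whose exons overlap RPRD1B on the opposite strand, rose by 5.42, CEACAM6 by 5.22 and DSCAM by 5.05 on the log2 scale. The largest falls were in CFC1 (-7.18), DDX53 (-6.56), FEV (-6.53), BCHE (-6.40) and L1CAM (-5.92). CFC1, a cofactor of Nodal signalling, fell from 108 ± 16.3 to 0.775 ± 0.269 CPM. Its near-identical copy CFC1B held 6 to 17 raw reads in the parental libraries, few beside the reads assigned to CFC1, and 0 in the liver-derived libraries. The division of reads between them is uncertain. FEV, an ETS transcription factor, fell from 20.4 ± 3.16 to 0.220 ± 0.105 CPM, and L1CAM, a neural adhesion molecule whose exons overlap ARHGAP4 and L1CAM-AS1, fell from 10.9 ± 1.80 to 0.163 ± 0.0790 CPM. All 10 genes kept their direction and their call in each alternative in which they were tested.

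Kallikrein genes fell among the androgen-regulated genes. KLK2, a secreted prostate protease, fell from 124 ± 12.7 to 13.6 ± 0.711 CPM (log2 fold change -3.18) and KLK4 from 526 ± 53.5 to 63.9 ± 0.825 CPM (-3.04). SLC43A1, an amino acid transporter, rose from 10.5 ± 1.11 to 69.6 ± 0.270 CPM (2.73). Named after their values were seen, KLK3, the gene of prostate-specific antigen, fell by 2.53 and TMPRSS2 fell by 2.58 on the log2 scale, whereas FKBP5 rose from 573 to 1026 CPM (0.84). Of 28 tested androgen-regulated genes, 8 rose, 12 fell and 8 did not pass; adjusted over the list alone, 8 rose and 13 fell. The list as a whole did not pass camera (adjusted p = 0.192).

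**Figure D2:**
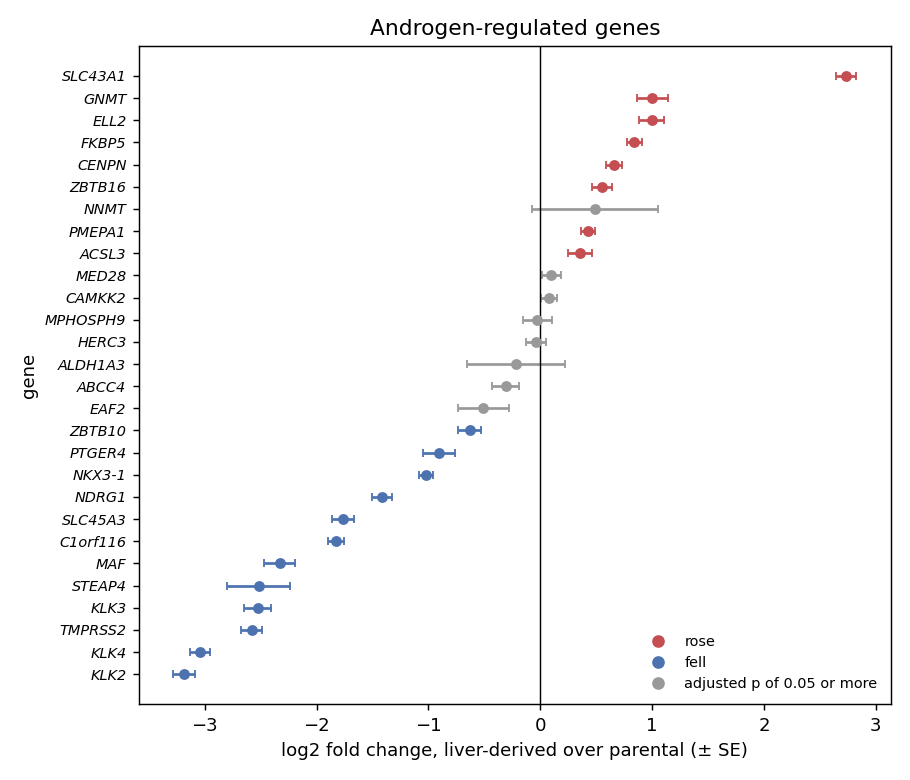
Fitted log2 fold change of each tested androgen-regulated gene, liver-derived over parental, with its SE as bars; red points rose, blue points fell and grey points had an adjusted p of 0.05 or more. Of the 28 genes, 8 rose and 12 fell, from KLK2 at -3.18 to SLC43A1 at 2.73.

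Prostate lineage transcription factors moved both ways. HOXB13 fell from 544 ± 56.0 to 325 ± 1.77 CPM (log2 fold change -0.74, edgeR adjusted p = 1.15e-04), GATA2 from 246 ± 30.2 to 33.9 ± 1.16 CPM (-2.86) and HOXA13 from 5.20 ± 0.884 to 0.400 ± 0.0982 CPM (-3.64). SOX9 rose from 19.6 ± 1.63 to 80.2 ± 1.90 CPM (2.03). FOXA1, a pioneer transcription factor, stood at 413 ± 8.76 and 377 ± 3.80 CPM (-0.13, adjusted p = 0.117); it was lower in each of 19 alternatives and passed in 6 of them, with adjusted p from 9.44e-06 without parental replicate 2 to 0.326 without liver-derived replicate 3. FOXA1 overlaps TTC6 on the opposite strand. Of 18 tested members, 6 rose, 6 fell and 6 did not pass, and adjusted over the list alone 6 rose and 6 fell; 10 fell without parental replicate 2. The list did not pass camera (adjusted p = 0.867).

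Genes of steroid and androgen metabolism changed in both directions. UGT2B11, which encodes an enzyme of glucuronidation and overlaps AC111000.4 on the opposite strand, rose by 4.36 (SE 0.20) on the log2 scale and UGT2B28, an enzyme of the same family, rose from 0.171 ± 0.121 to 3.89 ± 0.241 CPM (4.44). AKR1C3, a reductase that forms testosterone from androstenedione, fell from 29.3 ± 1.32 to 3.23 ± 0.591 CPM (-3.20). The UGT2B and AKR1C genes are families of close paralogs whose reads could be divided among members. Of 19 tested members, 7 rose, 1 fell and 11 did not pass; adjusted over the list alone, 8 rose and 1 fell. Without parental replicate 2, 3 fell, and without parental replicate 3, 2 fell. The list did not pass camera (adjusted p = 0.143).

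Neuroendocrine markers fell together. CHGA, the gene of chromogranin A, fell from 10.0 ± 1.70 to 0.536 ± 0.0665 CPM (log2 fold change -4.20), SVOP, a synaptic vesicle gene, from 4.26 ± 0.286 to 0.364 ± 0.182 CPM (-3.46) and CELF3, a neural RNA-binding protein gene, from 43.0 ± 6.84 to 8.30 ± 1.15 CPM (-2.38). Of 21 tested members, 1 rose, 16 fell and 4 did not pass; adjusted over the list alone, 1 rose and 17 fell. The single riser was SOX2, from 0.625 to 2.98 CPM, named after its values were seen. The list was lower by camera (adjusted p = 9.78e-06), and that call was lost with an estimated correlation (adjusted p = 0.124).

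More members rose than fell in the list of hypoxia-induced genes and in the joint list of the unfolded protein and integrated stress response. DDIT4, a stress-induced inhibitor of mTOR signalling and a member of both lists, rose from 32.0 ± 4.16 to 182 ± 1.20 CPM (log2 fold change 2.51). EGLN3, a prolyl hydroxylase, rose from 3.10 ± 0.437 to 17.2 ± 0.657 CPM (2.48) and STC2, a secreted glycoprotein, from 16.6 ± 1.10 to 54.9 ± 1.03 CPM (1.73). Of 22 tested hypoxia-induced genes, 13 rose, 3 fell and 6 did not pass (14 and 3 adjusted over the list alone; camera adjusted p = 0.00238, and adjusted p = 0.197 with an estimated correlation). Of 28 tested genes of the unfolded protein and integrated stress response, 15 rose, 6 fell and 7 did not pass (15 and 7 adjusted over the list alone; camera adjusted p = 0.0191, and adjusted p = 0.224 with an estimated correlation). CHAC1 rose by 1.90 and TRIB3 by 1.27 on the log2 scale; both are known targets of ATF4. The 6 members that fell, named after their values were seen, were the transcription factor gene ATF5, from 121 to 61.7 CPM (-0.97), which overlaps IL4I1 and NUP62 on the opposite strand, SDF2L1 (-0.44), DNAJC3 (-0.40), HERPUD1 (-0.37), HSPA5 (-0.36) and PDIA4 (-0.20). Without liver-derived replicate 1, and likewise without replicate 2, 3 members of that list fell.

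Mitochondrially encoded mRNAs were higher in the liver-derived libraries. Reads of the mitochondrial chromosome made up 1.19 to 1.38% of the parental counts and 1.67 to 1.72% of the liver-derived counts. Of 13 mRNAs, 12 rose and 1 did not pass, and adjusted over the list alone 13 rose (camera adjusted p = 2.78e-05, and adjusted p = 0.547 with an estimated correlation). MT-ND3 rose from 176 ± 2.04 to 373 ± 11.3 CPM (log2 fold change 1.08), MT-ND6 by 0.81 and MT-ATP6, which overlaps MT-ATP8 and MT-CO3, by 0.76. Of 35 nuclear genes of oxidative phosphorylation, 2 rose, 3 fell and 30 did not pass (2 and 1 adjusted over the list alone; camera adjusted p = 0.807); ATP5PO, which overlaps LINC00649, rose by 0.86. Without parental replicate 2, 14 of the 35 rose and 15 fell; the falls numbered 1 without parental replicate 1 and 0 without any 1 of the liver-derived libraries.

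Lists of hepatocyte, stromal, gastrointestinal and basal markers did not pass camera. Of 15 tested hepatocyte markers, 6 rose and 5 fell (6 and 6 adjusted over the list alone; camera adjusted p = 0.867), with a median log2 fold change of 0.22, a mean of -0.47 and a lower direction in camera. ASGR1, a hepatocyte lectin gene, fell from 1.47 to 0.178 CPM, and ALB, named after its values were seen, rose from 47.7 to 65.8 CPM (log2 fold change 0.46). Of 16 stromal, endothelial and leukocyte markers, 2 rose and 4 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.807), and LUM fell by 4.93 on the log2 scale. Gastrointestinal lineage genes numbered 8 that rose and 6 that fell among 16 (8 and 7 adjusted over the list alone; camera adjusted p = 0.753), led by CEACAM6, from 2.17 ± 0.203 to 81.0 ± 2.33 CPM. Basal and stem-like epithelial markers numbered 4 that rose and 7 that fell among 17 (4 and 9 adjusted over the list alone; camera adjusted p = 0.467).

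With all 6 libraries, structural and growth-related lists did not pass camera. Of 26 epithelial junction genes, 11 rose and 5 fell (11 and 5 adjusted over the list alone; camera adjusted p = 0.210), with a median of 0.0866, a mean of -0.0156 and a higher direction in camera, and OVOL1, an epithelial transcription factor, fell by 2.11 on the log2 scale; 3 fell without liver-derived replicate 1, and without parental replicate 2 the list passed as higher (adjusted p = 0.0342). Of 28 mesenchymal and invasion genes, 2 rose and 7 fell (2 and 7 adjusted over the list alone; camera adjusted p = 0.725), led by L1CAM; 4 rose without parental replicate 3. Of 35 cell cycle genes, 2 rose and 8 fell (1 and 6 adjusted over the list alone; camera adjusted p = 0.801), and CDC20 fell from 214 ± 24.1 to 146 ± 2.27 CPM (-0.55). Without parental replicate 2, 11 cell cycle genes rose and 15 fell, and without any 1 liver-derived library 0 rose and 4 to 5 fell.

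Metabolic lists moved both ways. Of 23 glycolysis genes, 10 rose and 3 fell (10 and 3 adjusted over the list alone; camera adjusted p = 0.344), and PFKFB4, which overlaps UCN2, fell from 11.2 ± 1.31 to 5.57 ± 0.685 CPM. Without parental replicate 2, 15 of them rose, 5 fell and the list passed as higher (adjusted p = 0.0330), whereas 4 rose without any 1 of the other libraries. Of 25 cholesterol synthesis genes, 7 rose and 5 fell (7 and 5 adjusted over the list alone; camera adjusted p = 0.725), and MSMO1 rose from 91.2 ± 19.3 to 174 ± 2.88 CPM (0.93); 12 rose and 10 fell without parental replicate 2, and 2 to 3 fell without any 1 of the other libraries. Of 29 genes of fatty acid synthesis and oxidation, 8 rose and 12 fell (8 and 14 adjusted over the list alone; camera adjusted p = 0.807), with a median of -0.15, a mean of 0.0461 and a lower direction in camera, and 5 rose without liver-derived replicate 3. PPARGC1A, a transcriptional coactivator of mitochondrial genes, rose from 0.177 ± 0.00739 to 2.71 ± 0.196 CPM (3.91).

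With all 6 libraries, lists of immune, p53 and immediate early genes did not pass camera. Of 32 interferon response genes, 9 rose and 9 fell (9 and 9 adjusted over the list alone; camera adjusted p = 0.956), and HERC5 fell from 2.96 to 0.643 CPM (log2 fold change -2.22). Of 22 antigen presentation genes, 4 rose and 6 fell (4 and 6 adjusted over the list alone; camera adjusted p = 0.807), and PSMB9, a subunit of the immunoproteasome, fell from 6.44 to 1.64 CPM (-2.00); 7 rose without parental replicate 2. Of 15 NF-kappaB and inflammatory genes, 3 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.807), and ICAM1, which overlaps ICAM4-AS1 on the opposite strand, fell by 1.46; 4 fell without parental replicate 2. Of 24 p53 target genes, 9 rose and 8 fell (9 and 8 adjusted over the list alone; camera adjusted p = 0.725), with a median of -0.00813, a mean of 0.20 and a higher direction in camera; 5 fell without liver-derived replicate 1. GADD45A, a growth arrest gene, rose from 30.3 ± 1.15 to 436 ± 4.43 CPM (3.85). Of 21 immediate early genes, 9 rose and 2 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.192), and KLF4 rose by 1.27; without parental replicate 2, 14 rose and the list passed as higher (adjusted p = 0.0253).

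**Figure D3:**
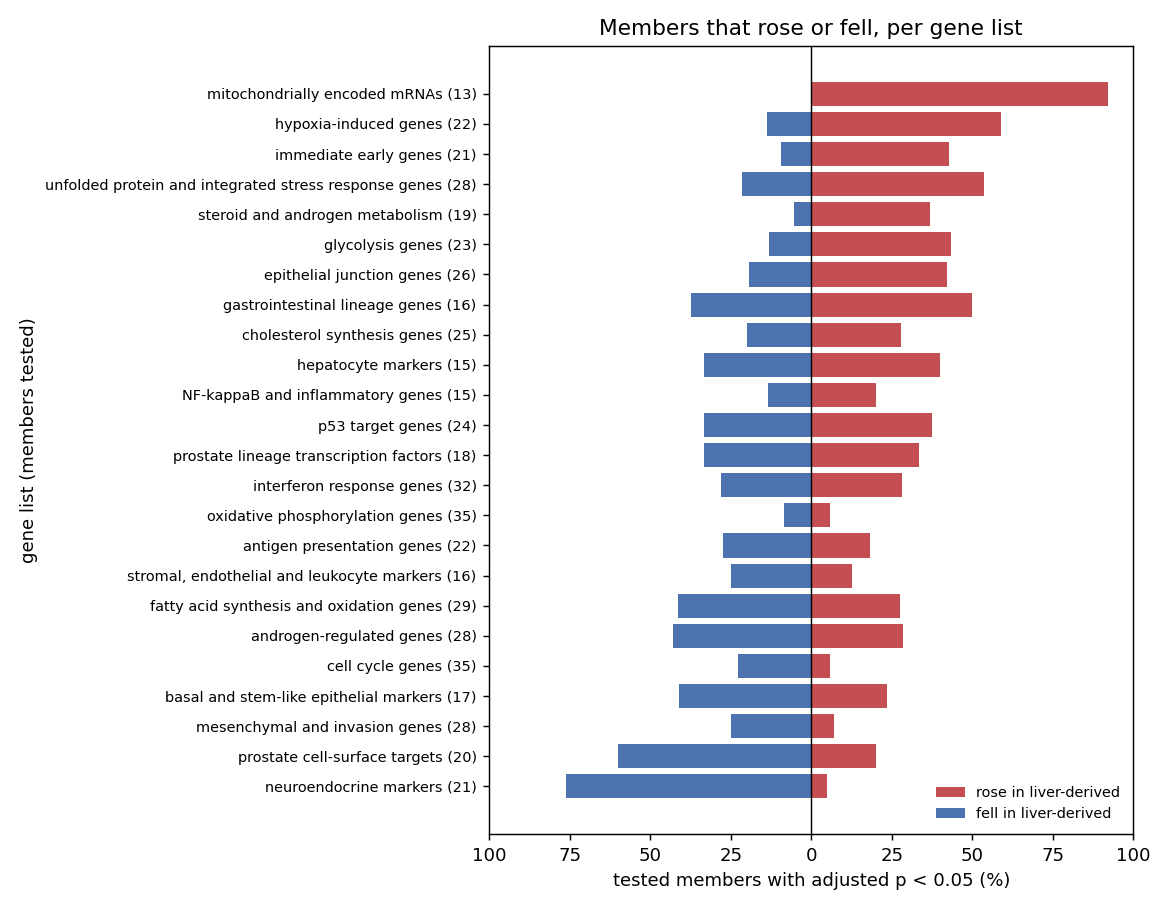
Percent of the tested members of each gene list that rose (red, to the right) or fell (blue, to the left) in liver-derived against parental cells at an edgeR adjusted p under 0.05, with the number tested in parentheses. Neuroendocrine markers (1 rose and 16 fell of 21) and mitochondrially encoded mRNAs (12 rose of 13) lie at opposite ends.

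The authors' TPM table gave the same direction for FOLH1, with a change of -1.75 (SE 0.13) on the log2(TPM + 1) scale and an adjusted p of 1.19e-04 by limma. Of 17453 genes tested on that scale, 6541 passed, 2699 higher and 3842 lower. The TPM values are the counts rescaled by gene length, so this is not an independent measurement.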

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

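The alternatives that corrected GC content, left out both second replicates, left out chromosome 21 or estimated the correlation for chromosomes were chosen after the data were seen. FOLH1 stayed lower and past the threshold in all 19 alternatives, at -1.85 to -1.66 on the log2 scale. Of 50 genes named by the rule, 48 kept direction and call in every alternative in which they were tested. None of the 50 turned direction, and FOXA1 passed in 6 of 19. Where no cause is named below, the cause was not tested.

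Leaving out 1 library moved the count of changed genes between 5600 and 11870 (higher 2432 to 5714, lower 3168 to 6156), highest without parental replicate 2; leaving out both second replicates gave 11677, with 5759 higher. The deviation of parental replicate 2 from the other parental libraries followed transcript GC content across 11533 genes (Spearman rho 0.892; genes are not independent). Replicates 1 and 3, each set against a mean that includes replicate 2, gave -0.821 and -0.845, and the difference between replicates 1 and 3 gave 0.158; rho was -0.136 to 0.165 in the liver-derived libraries. The group difference gave rho -0.167 with GC content and 0.0781 without that library. Changes of 2-fold or more fell to 1754 (573 higher, 1181 lower) with the CPM filter, which tests fewer genes, and to 1406 (378 higher, 1028 lower) with glmTreat, which tests against that size.

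Camera called 5 lists, 5 to 8 without 1 library (8 without parental replicate 2), 0 with an estimated correlation (4 at an unadjusted p under 0.05) and 15 with fry, which tests whether the genes of a list move, on balance, one way and not against other genes. With an estimated correlation the adjusted p was 0.197 for hypoxia, 0.547 for mitochondrial mRNAs, 0.124 for neuroendocrine, 0.224 for cell-surface and 0.224 for stress response genes. Fry passed androgen-regulated genes (9.45e-06), cell cycle (6.15e-04), cholesterol (0.0314), epithelial junction (0.0486), gastrointestinal (6.15e-04), hepatocyte (6.15e-04), p53 (3.69e-05), lineage factors (0.0109) and steroid metabolism (0.00807), and turned fatty acid genes to higher (0.0109). GC correction passed epithelial junction and immediate early genes (0.0359 each), leaving out both second replicates passed immediate early genes (0.0270), and no filter passed steroid metabolism (0.0180). Without 1 library the adjusted p ranged from 0.0342 to 0.437 for epithelial junction, 0.0330 to 0.661 for glycolysis and 0.0253 to 0.437 for immediate early genes.

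Lists near 0 turned direction without passing: hepatocyte markers with GC correction (0.959), both second replicates left out (0.947), library size only (0.979), no filter (0.888) and each parental library left out; interferon genes with chromosome 21 left out (0.842), library size only (0.915), no filter (0.888) and each library but liver-derived replicate 2 left out; NF-kappaB genes with both second replicates left out (0.761), fry (0.678) and liver-derived replicate 2 left out (0.792); antigen presentation (0.987) and stromal markers (0.848) with the CPM filter; stromal markers with GC correction (0.971); oxidative phosphorylation with both second replicates left out (0.761) and parental replicate 2 left out (0.978). Over all 6 fits without 1 library, turned or not, the adjusted p ranged from 0.807 to 0.988 for hepatocyte, 0.800 to 0.987 for interferon, 0.702 to 0.889 for NF-kappaB and 0.661 to 0.978 for oxidative phosphorylation genes. Chromosome calls numbered 1, and 2 with the CPM filter, GC correction or both second replicates left out, where chromosome 3 was lower; 2 with an estimated correlation, where chromosome 12 was higher (median 0.0926, adjusted p = 0.0380); 1 to 2 without single libraries, 2 without parental replicate 2, where chromosome 3 was lower; and 0 with chromosome 21 genes left out.

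With the replicate number as a block, 7052 genes were called and no list or chromosome call changed. Same-numbered libraries did not deviate together (correlations -0.00842, 0.00925 and 0.0722), so the numbers were not taken as pairs, and of the 3 numbers only 3 had its highest correlation with its own number. The TPM count ranged from 4535 to 9527 over its alternatives. In counts simulated at these depths, with each gene drawn on its own at its estimated dispersion, 56.7% of genes changed by 1.5-fold were recovered. For genes changed by 2-fold the share was 64.2%. Far fewer genes were changed in the simulation than were called in the data, so these shares need not hold for the real comparison. The joint shift of parental replicate 2 with GC content was not simulated, so false calls from it were not assessed. Depth was not varied.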

Other observations

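The tests of GC correction, of the second list of amino acid response genes and of other splits of the libraries were set before their results were seen; the other tests reported here were chosen after the result was seen, as were the genes and families named. SLC7A5 and SLC3A2, which encode the light and heavy chains of the LAT1 amino acid transporter, rose by 5.01 (SE 0.10) and 3.90 (SE 0.08) on the log2 scale, from 263 ± 28.4 to 8495 ± 110 CPM and from 175 ± 15.5 to 2616 ± 50.1 CPM (SD, n = 3). SLC7A5 overlaps AC126696.2 on the opposite strand. SLC7A11, another amino acid transporter gene, which overlaps SLC7A11-AS1, rose from 38.3 to 70.5 CPM (0.88). ASNS (1.26), PSAT1 (1.02) and PHGDH (0.98), enzymes of asparagine and serine synthesis, rose as well.

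Among 265 families of protein-coding genes sharing a symbol stem, with 8 or more tested members, camera called 5, and 0 with an estimated correlation (7 at an unadjusted p under 0.05). Of 10 kallikrein genes 9 fell (camera adjusted p = 3.95e-05), led among abundant members by KLK11, from 40.2 to 0.806 CPM. Of 12 PCDH genes 9 fell (3.64e-04), with PCDH7 from 57.5 to 21.3 CPM, and of 16 CDH genes 9 fell and 1 rose (0.0160), with CDH6 from 44.7 to 1.91 CPM while CDH1, overlapping AC099314.1, rose by 0.26 on the log2 scale. Of 11 UGT genes 7 rose and 1 fell (0.0160), and of 14 RGS genes 10 fell and 2 rose (0.0232). All 5 calls had an adjusted p of 0.995 with an estimated correlation.

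The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split called 7476 genes and the highest other split 0 by edgeR (at most 419 at an unadjusted p under 0.05); for changes of 2-fold or more the counts were 2658 and 0, for lists 5 and 3, and for families 5 and 4. Chromosome calls behaved otherwise: the real split gave 1 and another split 13, and all 10 splits gave at least 1. The highest counts, 10, 11 and 13, came from the splits that part parental replicate 2 from parental replicates 1 and 3. Each split other than the real one also holds part of the group difference, and that part was not separated from differences among libraries. Such a split puts libraries of both groups on each side, which widens the spread within a side. Few gene calls were thereby fixed in advance, so their low number in the other splits says nothing about chance. The splits with as large a result as the real one, counting the real one itself, numbered 1 for genes, 2-fold changes, lists and families.

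Genes of chromosome 21 were higher in the liver-derived cells, with a median log2 fold change of 0.54 over 225 tested genes (camera adjusted p = 1.90e-09, and adjusted p = 0.00713 with an estimated correlation, which also called chromosome 12 as higher). Against a GC artifact, the median was 0.55 after GC correction, and against a few strongly changed genes, 76.9% of the genes were higher. Against a local cluster, the lowest of 3 parts of 75 genes each, in order of position, had a median of 0.32. The shift was uneven, with medians of 0.22 to 0.73 over windows of 50 consecutive tested genes on this chromosome. Genes with a mean CPM of at least 5 had a median of 0.61, or 1.53-fold, and 86.7% of these 113 genes were higher, against 51.1% on other chromosomes. A candidate explanation is an extra copy of chromosome 21 in the liver-derived cells; DNA was not measured here, so it remains a hypothesis. TMPRSS2 fell and DSCAM rose far beyond this shift, and both lie on the chromosome.

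FOLH1 and the kallikreins fell together, and a loss of either chromosome segment stays open: the 22 neighbours within 2 Mb of FOLH1 had a median log2 fold change of -0.0264, but the 3 within 1 Mb had -2.95. The 146 neighbours within 2 Mb of the kallikreins had -0.0612, but the 17 within 0.25 Mb had -0.96. Kallikreins with a mean CPM of at least 5 ranged from -5.60 to -1.75. The 50-gene window that holds the kallikreins had -0.82, the lowest of 18059 windows. That window counts the kallikreins themselves, so it is not separate support for a loss. Admixture of other cells would lower epithelial genes alike, and the epithelial junction genes had a median of 0.0866; GC content is argued against by a FOLH1 change of -1.79 after correction. A fall of all androgen-regulated genes is argued against because 28.6% of the tested members rose. A fall with exceptions stays open. By 2-fold or more, 10 members fell and 2 rose, and fry passed the list as lower (adjusted p = 9.45e-06), whereas camera did not pass it. A change in the regulation of part of these genes in the liver-derived cells may also remain, and was not tested.

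For SLC7A5 and SLC3A2, a gain of a segment of 2 Mb to each side is argued against by their neighbours. The 61 neighbours of SLC7A5 had a median log2 fold change of 0.0786 and the 115 of SLC3A2 had -0.0784. Within 0.25 Mb the 29 neighbours of SLC3A2, with 0.26, argue against a gain of that length there. A gain of that length with SLC7A5 stays open, since its 8 neighbours had a median of 0.86 and quartiles of 0.50 and 3.69. The SLC7A5 pseudogenes held 0.0521% of its liver-derived CPM. How reads were divided between SLC7A5 and these copies is not known. This low share therefore cannot decide whether SLC7A5 was assigned reads of a pseudogene. A second list of 24 amino acid response genes without transporters, written before their values were looked up, had a median of 0.65; 22 rose and 0 fell (camera p = 4.02e-11, and p = 0.00185 with an estimated correlation). AARS1 rose by 0.78 and GPT2 by 1.28 on the log2 scale. This is consistent with a part in an amino acid response, as a hypothesis, but ATF5, a stress response gene outside that list, fell by 0.97, the rise of SLC7A5 exceeds that of each gene of the list, and what sets it apart was not tested.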
